A study of Drosophila melanogaster with 2 samples.

How the data were processed

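Chromatin immunoprecipitation and sequencing was done on whole embryos of a fly line that expresses CTCF with GFP at its C terminus, with an antibody against GFP. The 2 samples form 1 group, CTCF-GFP embryo, and carry the biological replicate numbers 2 and 3 of the labels. Chromatin was sonicated, with a size range of 200 to 800 per the labels. The authors' peak lists were the starting point: for each of the builds dm6 and dm3, per the file headers, a relaxed list per replicate, a relaxed list from both replicates pooled, and a list thresholded by the irreproducible discovery rate (IDR), here called the reproducible peaks. The relaxed lists were made from alignments and a control and served as input to the IDR step, per the file headers. The aligner, the peak caller and their versions are not given in the sources used here, and the control libraries, signal tracks and alignments were not used here.

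Each deposited peak has a start, an end, a summit, a signal value and a q-value. The signal is a score of the authors' peak caller with no scale stated in the file headers, and it was used to rank and describe peaks within a list. The deposited -log10 q column was not used for ranking, because 5147 of the 5443 reproducible dm6 peaks share its highest value. Each relaxed list holds exactly 30000 peaks, so its length says nothing of depth. Read depth per sample is not given in the sources used here, and intervals cover counting error over peaks or genes only. Some intervals are listed again with another summit (95 among the reproducible dm6 peaks), and every listed summit was kept.

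Arm sequences came from the RefSeq assembly of the dm6 build, and every dm6 peak listed on an arm ended within it; 1 peak of replicate 3's relaxed list and 1 of the pooled relaxed list were on no arm. Genes and transcripts came from Ensembl release 115 with FlyBase annotation 6.54. The 17683 FlyBase genes on X, 2L, 2R, 3L, 3R and 4 were used, and 6290 other annotation entries, such as transposable elements, were left out. Lists on dm3 were compared by counts only, and no coordinates were converted. Coordinates are 1-based.

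The replicates' strongest 5443 peaks were called shared where summits lay within 100 bp, and 1000 circular shifts along each arm gave the chance value (one-sided permutation). Pearson and Spearman correlations were taken across peaks, which are not independent replicates, and no test across samples was possible with 2 samples. A promoter was the 1 kb on either side of a transcript start, and each summit was put in 1 class in the order promoter, 5' UTR, coding, 3' UTR, other exon, intron, intergenic. Shares were set against the 1000 shifts (two-sided permutation). Motifs were searched on both strands within 50 bp of the summit and in windows of equal width 500 bp to the left and right (exact McNemar tests, the larger p kept). Gene lists were compared with all other genes by two-sided Fisher's exact tests for a summit within 1 kb of a transcript start. Arm densities used an exact binomial test and exact Poisson intervals, and the bithorax complex was compared with windows of its own length every 10000 bp. Benjamini-Hochberg adjustment was applied over the 7 classes, the 13 motifs and the 18 gene lists separately, and 0.05 was the threshold. Peaks near each other and genes that share a promoter are not independent, so p-values over peaks and genes describe these lists and not variation between embryos.

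The design, motifs, gene lists and the rule for named genes were fixed before the data were examined. Named were the 20 reproducible peaks with the highest signal, each with the gene of the nearest transcript start, every Hox gene, every architectural protein gene with a summit within 1 kb of a start, every peak of the bithorax complex, and for each other list up to 4 members with the highest signal; 1 gene under this rule is not reported here. Of 33 Polycomb and Trithorax group names 32 were found, and 4 names in other lists were matched through synonyms in a RefSeq gene table. Alternatives were other summit distances, only the 2721 strongest peaks, each replicate alone, the strongest pooled peaks with no IDR step, other promoter distances, protein-coding genes only, other motif forms and windows, other backgrounds and gene length quintiles. Added after the data were examined were local shifts of 10 to 100 kb, merging of overlapping peaks, gene lists with motif peaks only, and settings for the feature classes, the other motifs and the motif share by rank. The statistics were tested on simulated data with planted answers, and all 9 checks passed. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.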

Results

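CTCF is a zinc finger protein that binds DNA and is found at insulators and domain boundaries of animal genomes. Its binding was mapped by chromatin immunoprecipitation and sequencing in whole embryos of Drosophila melanogaster, 0 to 16 h old and of mixed sex. The embryos came from a transgenic fly line in which CTCF carries GFP at its C terminus, and the immunoprecipitation used an antibody against GFP. The series held 1 group with 2 biological replicates, numbered 2 and 3 in the labels, and no untreated sample, so it implied no contrast between conditions. The questions addressed here were where tagged CTCF sat in the embryonic genome, how well the replicates recovered the same sites, and which sequences and genes marked them. Positions are on dm6 throughout. The number of reads behind each peak was not given in the sources used here, so intervals cover counting error over peaks or genes only.

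Tagged CTCF had 5443 reproducible peaks, a list the authors made from both replicates by the irreproducible discovery rate. Each peak is a listed summit, and overlapping peaks merge into 5098. All 5443 lay on the chromosome arms, with 1009 on X, 995 on 2L, 1035 on 2R, 1118 on 3L, 1253 on 3R and 33 on chromosome 4. Peak strength, the authors' signal value, was very uneven: it ran from 195 to 89235 with a median of 345, and the strongest 10% of the peaks held 76.4% of the summed signal. Each replicate's own list and the pooled list held 30000 peaks, and the 5443 reproducible peaks were the 5443 strongest of the pooled list. On the older build dm3 the reproducible list held 4845 peaks, and the ratio of dm6 to dm3 peaks was between 1.12 and 1.13 on each of X, 2L, 2R, 3L and 3R.

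The replicates recovered largely the same sites. Of the 5443 strongest peaks of replicate 2, 78.3% (95% Wilson interval 77.2 to 79.4%) had a summit within 100 bp of one among the 5443 strongest of replicate 3, against 0.818% after circular shifts along each arm (one-sided permutation p = 0.000999, the smallest that 1000 shifts can give). Among the 2721 strongest peaks of each replicate, 86.9% were shared. Of the reproducible peaks, 5233 (96.1%) had a summit within 100 bp in both replicates, and across these peaks the log2 signals correlated with Pearson r = 0.973 and Spearman rho = 0.860. The reproducible list was itself thresholded on agreement between these 2 replicates, so this share and these correlations are not independent evidence of their agreement. The median log2 ratio of replicate 3 to replicate 2 was 0.10, with an SD of 0.42 across peaks. That SD was 0.29 over the 2686 matched peaks above the median pooled signal and 0.52 over the 2547 below it. Among those below it r was 0.020 and rho 0.094, but the pooled signal was close to the sum of the replicates' signals (median ratio 1.00), so a split on it lowers the correlation of weak peaks by itself. Peaks within a library are not independent replicates.

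The 20 strongest sites had signals from 41822 to 89235 and ranked no lower than 20 in replicate 2 and 23 in replicate 3. Of these, 9 lay within 1 kb of a transcript start, 10 carried the exact CTCF core motif within 50 bp of the summit and 18 carried it with at most 1 mismatch. The strongest (signal 89235; 41977 in replicate 2 and 47301 in replicate 3) was intergenic on 3R, from 14390670 to 14392122, and 5063 bp from the nearest transcript start, that of the microRNA gene mir-2281. It held 2 copies of the motif on the minus strand, CGTGTAGGTGGCGCTTGCC around positions 14391414 to 14391422 and GTTGTAGATGGCGCCAAGT around 14391448 to 14391456, each given with 5 bp on either side of the core. The second (61078) was intergenic on 3L from 5869218 to 5870471, 1704 bp from CG5568, with 2 copies of the motif at 1 mismatch and no exact copy.

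The third strongest site in the embryo was at the CTCF gene itself (FBgn0035769, 3L from 7353578 to 7356713, minus strand). Its summit at 7356548 lay 165 bp inside the transcript start, in an intron of CTCF and an exon of the antisense RNA gene asRNA:CR45822, with a signal of 59120 (29666 in replicate 2 and 29350 in replicate 3). The motif copy there was CCCGAAGAGGGCGCTTATC around 7356518 to 7356526. The next peaks lay 274 bp from mtSSB (58474), which encodes the single-stranded DNA binding protein of mitochondria, and 326 bp from dco (57257), which encodes the casein kinase of the circadian clock. The mtSSB site carried the motif neither exactly nor with 1 mismatch, while the dco site carried 3 exact copies. Sites inside genes included coding sequence of otp (53840), a homeobox gene, the 5' UTR of Mef2 (48410), which encodes the myogenic transcription factor, an intron of TfAP-2 (47651), an intron of EcR (43888), the ecdysone receptor gene, and an intron of RapGAP1 (43422). The remaining sites among the 20 were nearest to CG10357 (3' UTR), sgll, CG10600, CG13896, Gr89a, CG10651, lncRNA:CR45277, crp, CG15282 and for, with signals between 41822 and 52334.

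Gene promoters held most reproducible peaks, though only 34.5% of those with the CTCF core motif. No sample without the tag was used here, so signal common to promoters was not set apart from CTCF binding. Of the 5443 summits, 3415 (62.7%, 95% Wilson interval 61.4 to 64.0%) lay within 1 kb of an annotated transcript start, against 23.6% of shifted summits (two-sided permutation p = 0.002, the smallest that the shifts can give). Coding sequence outside promoters held 1.47% of summits against 10.5% shifted, 3' UTRs 1.69% against 3.71%, introns 20.9% against 36.1% and intergenic sequence 12.5% against 25.1%; each share was lower than shifted (permutation, adjusted p = 0.0028 over 7 classes, the smallest they can give). The shares of 5' UTRs and other exons outside promoters, 0.349% and 0.312%, did not pass the test. Between the starts of divergent gene pairs at most 1 kb apart fell 766 summits (14.1%, 95% Wilson interval 13.2 to 15.0%), against 0.821% of shifted summits (two-sided permutation p = 0.002). Every such span lies within the promoter class, and the shifts were not matched for it. Whether divergent pairs were preferred over other promoters was therefore not tested. Peaks were also clustered, with a median spacing of 10089 bp against 17020 bp for random placement along the arms and 14402 bp for placement within 1 Mb bins (two-sided permutation p = 0.002 for each).

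**Figure D1:**
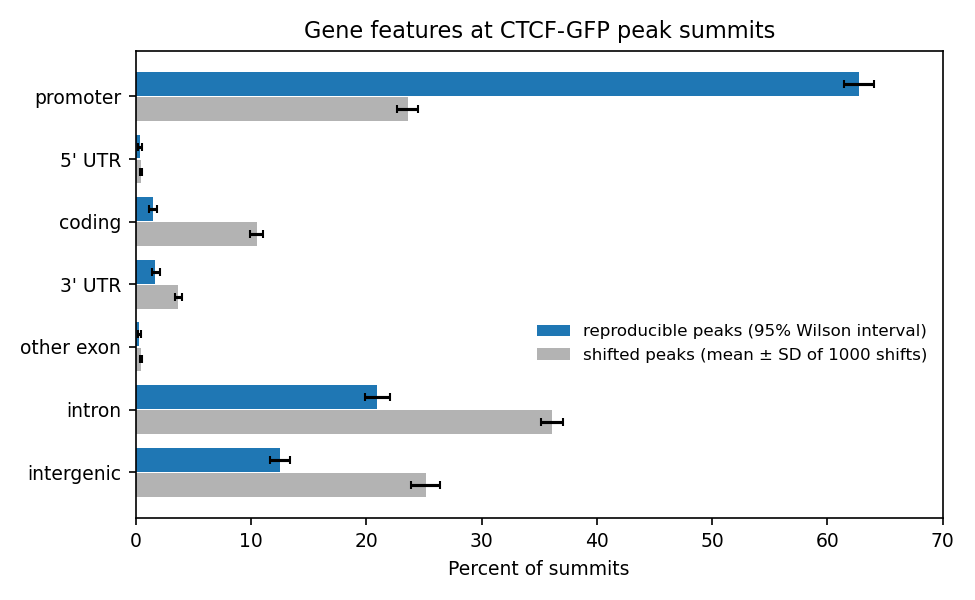
Percent of the 5443 reproducible summits in each gene feature (blue, with 95% Wilson intervals) beside circularly shifted summits (grey, mean ± SD of 1000 shifts), each summit counted in 1 class and the promoter class taken first. Promoters held 62.7% of summits against 23.6% shifted, and the coding, 3' UTR, intron and intergenic shares lay below the shifted shares.

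The CTCF core motif AGRKGGCGC marked a minority of the sites, and chiefly the strong ones. It lay within 50 bp of the summit in 692 peaks (12.7%, 95% Wilson interval 11.9 to 13.6%) against 0.138% of windows 500 bp to either side, a 92.3-fold difference (exact McNemar test, p = 4.56e-188, the larger of the values for the 2 sides). The same bases written in reverse order, a control of equal composition, occurred in 0.110% of peaks and 0.119% of flanks. The motif centre was a median of 14 bp from the summit. Its share fell from 50.6% in the strongest 10th of the peaks to 37.2%, 16.5% and 8.27% in the next ones and to 1.10% in the weakest (Spearman rho = 0.41 between signal and motif presence across peaks, permutation p = 1e-05, the smallest that 100000 permutations can give). With 1 mismatch allowed, 82.9% of the strongest 10th carried it. Among the 23283 pooled peaks that overlapped no reproducible peak, the exact motif was in 0.490%.

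**Figure D2:**
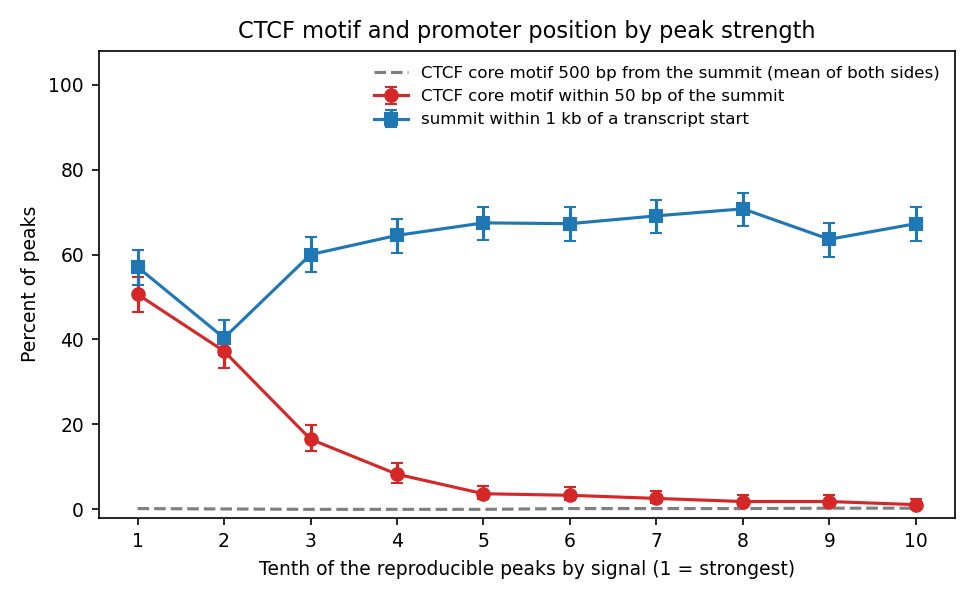
Percent of peaks with the CTCF core motif within 50 bp of the summit (red circles) and percent within 1 kb of a transcript start (blue squares) in 10 equal bins of the reproducible peaks ordered by signal, strongest first, with 95% Wilson intervals; the dashed grey line is the motif share 500 bp from the summit. The motif share falls from 50.6% to 1.10%, while the promoter share is lowest, at 40.4%, in the second bin.

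Sites with and without the motif were placed differently. Of the 692 motif peaks 239 (34.5%, 95% Wilson interval 31.1 to 38.2%) were within 1 kb of a transcript start, compared with 3176 of the 4751 others (66.8%, 65.5 to 68.2%; odds ratio 0.262, 95% interval 0.221 to 0.309, two-sided Fisher's exact test p = 2.80e-58). Motif peaks had a median signal of 2137 and the others 314. Within tertiles of signal the odds ratio was 0.303 (Mantel-Haenszel), in the same direction.

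Among the 13 motifs fixed before the data were examined, some core promoter and insulator motifs were also more frequent at summits than in flanks. The flanks were not matched for distance to a transcript start, so an excess of promoter motifs can follow from promoter position alone. DRE (TATCGATA, bound by Dref and BEAF-32) was in 2.83% of peaks against 0.312% of flanks, 9.06-fold, with an adjusted exact McNemar p of 3.16e-27. Motif 1 (GGTCACAC, bound by M1BP) was in 2.48% against 0.257%, 9.64-fold (adjusted exact p = 5.41e-25), Ohler 6 in 0.698% against 0.119% (adjusted exact p = 0.000115), and the su(Hw) core in 2.46% against 0.781% (adjusted exact p = 2.91e-10). The Polycomb recruiter Pho had its motif in 15.2% against 8.66% of windows (adjusted exact p = 3.97e-24), but its sequence overlaps the CTCF core by construction. In peaks without the exact core it was in 10.2% against 8.39% (adjusted exact p = 0.0137). Those peaks carried the core with 1 mismatch 8.80 percentage points more often than their flanks. Such copies can match Pho too, so the remaining Pho excess cannot be told apart from CTCF sites. The motif of Zelda, the activator of the zygotic genome, was rarer at summits, 0.257% against 0.615% (adjusted exact p = 0.0262), a difference that did not pass the test in the strongest peaks of either replicate alone or among the 2721 strongest reproducible peaks. GAGA, E-box, Inr and TATA box motifs did not pass the test.

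Genes with a CTCF site near a transcript start were 4317 of 17683 (24.4%), and of 18 gene lists 6 had peaks more often and 3 less often than other genes (two-sided Fisher's exact tests, adjusted over the lists). The other genes were not matched for promoter activity, and no sample without the tag was used here. Genes of cytoplasmic ribosomal proteins stood highest: 68 of 85 (80.0%, 95% Wilson interval 70.3 to 87.1%) had a peak, against 24.1% of other genes (adjusted exact p = 8.71e-26). Among the strongest were those at RpS21 (22260), RpS28a (18822) and RpS19a (7462), all with the CTCF motif, although only 5 of the 85 genes had a motif peak. Of cell cycle genes 18 of 31 had a peak (adjusted exact p = 0.00029), led by CycB (14059), a mitotic cyclin, then Cdk2 (1206), Cdk4 (848) and CycB3 (411). Circadian clock genes had peaks at 7 of 10 (adjusted exact p = 0.00776), including dco (57257), per (3451), sgg (2452) and Pdp1 (485). Of mitochondrial ribosomal protein genes 27 of 73 had a peak (adjusted exact p = 0.0385), with mRpL1 (1233), mRpS23 (1199), mRpS10 (1172) and mRpL41 (1015) the strongest.

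Genes that encode chromatin architectural proteins had peaks more often as well, at 14 of 27 (adjusted exact p = 0.00728). Apart from CTCF, peaks were at pzg (12757), Chro (998), pita (648), Top2 (592), Cp190 (546), Dref (479), Ibf1 and Ibf2, which share 1 peak (476), fs(1)h (435), su(Hw) (304), M1BP (294), Trl (254) and BEAF-32 (227). Only those at CTCF and pzg carried the CTCF motif. Polycomb and Trithorax group genes had peaks at 15 of 32 (adjusted exact p = 0.0138), with Bap170 (1025), ph-p (943), osa (817) and Pc (647) the strongest and no motif peak among them.

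Genes of chemosensory receptors and of cuticle proteins rarely had CTCF sites near their starts. Odorant and gustatory receptor genes had a peak at 3 of 119 (2.52%, adjusted exact p = 2.99e-10), namely Or67b (487), Or88a (267) and Gr97a (202). Their odds ratio of 0.0794 was 0.134 without replicate 2 (5 of 119), 0.0491 at 200 bp, 0.0334 at 500 bp and 0.368 at 2 kb (17 of 119), past the exact test each time. Cuticular Rebers-Riddiford protein genes had one at 6 of 70 (8.57%, adjusted exact p = 0.00413), with Cpr31A (1289), Cpr51A (886), Cpr47Ec (241) and Cpr67Fa2 (239) the strongest; their odds ratio of 0.289 was 0.189 without replicate 3, 0.0843 at 200 bp and 0.177 at 500 bp, each past the exact test. No replication-dependent histone gene of 111 had a peak (adjusted exact p = 4.04e-13). These are near-identical copies on 1 arm, and how reads that match several copies were handled is not given, so that value is uncertain.

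The other lists did not pass the test. Peaks were at 2 of 16 gap and pair-rule genes, prd (2562) and cnc (626), at 7 of 21 segment polarity and morphogen genes, led by tkv (916), Mad (424), gsb-n (330) and put (305), and at 13 of 38 proteasome genes, led by Rpt4R (732), Rpn10 (675), Rpn9 (411) and Rpt6 (328). Neuronal genes had peaks at 4 of 20, nrv3 (3771), elav (850), Syx1A (314) and Sh (290), and muscle genes at 5 of 19, led by Mef2 (423 at its start), Tm1 (365), Msp300 (283) and how (259). Dosage compensation genes had peaks at 4 of 8, the noncoding RNAs lncRNA:roX1 (416) and lncRNA:roX2 (208), msl-2 (221) and msl-3 (203). Transfer RNA genes had them at 68 of 295, where neighbouring copies share peaks (tRNA:Glu-TTC-1-6, tRNA:Glu-TTC-1-5 and tRNA:Glu-CTC-2-1, 35586; tRNA:Thr-AGT-1-4, 24035), and chorion and vitelline membrane genes at 1 of 16, Vm32E (12160).

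Several of these calls ended under other settings. Within gene length quintiles (Mantel-Haenszel) the architectural (odds ratio 2.51), Polycomb and Trithorax (1.75) and circadian lists (4.13) no longer passed the test, and transfer RNA genes, with an odds ratio of 0.926 in the main test, were higher (2.00). With starts at most 200 bp away transfer RNA genes were lower (odds ratio 0.513, adjusted exact p = 0.00256) and dosage compensation genes higher (adjusted exact p = 0.0390). Architectural genes did not pass the test there (odds ratio 2.46 against 3.34 in the main test, adjusted exact p = 0.0875). Circadian genes fell to 2 of 10 at that distance (odds ratio 1.46 against 7.23, adjusted exact p = 0.777) and to 5 of 10 at 500 bp (adjusted exact p = 0.0670), but the odds ratio was 11.4 among the 2721 strongest peaks (adjusted exact p = 0.00155). At 2 kb the Polycomb and Trithorax call ended (odds ratio 2.23 against 2.74 in the main test, adjusted exact p = 0.0663). The call for mitochondrial ribosomal proteins, with an odds ratio of 1.82 in the main test, ended in 4 settings. These were 2 kb (1.64, adjusted exact p = 0.0754), merged overlapping peaks (1.73, adjusted exact p = 0.0572) and protein-coding genes alone (1.56, adjusted exact p = 0.125). The last was the 2721 strongest peaks, where the odds ratio was 1.20. The cell cycle call ended among the 2721 strongest peaks (odds ratio 1.82 against 4.30 in the main test, adjusted exact p = 0.375). No call remained when peaks with the CTCF motif alone were used.

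**Figure D3:**
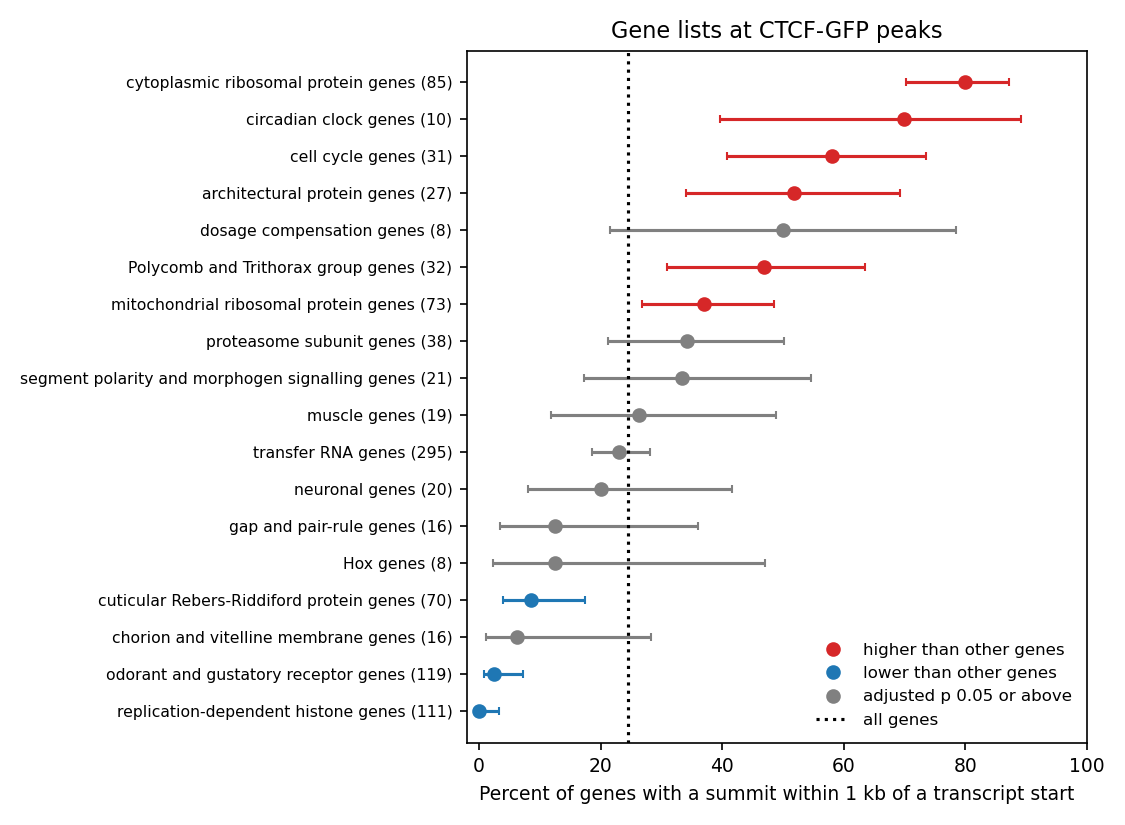
Percent of each list's genes with a reproducible summit within 1 kb of a transcript start, with 95% Wilson intervals and the number of genes in parentheses; the dotted line is the share of all genes, 24.4%. Cytoplasmic ribosomal protein genes stand at 80.0% and odorant and gustatory receptor genes at 2.52%; red and blue mark lists higher and lower than other genes (adjusted Fisher's exact tests), grey the rest.

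Of the 8 Hox genes, which set segment identity, only Abd-B (3R from 16927212 to 16972236, minus strand) had a CTCF summit within 1 kb of a transcript start (signal 8670, 671 bp away, with the motif); the list did not pass the test (adjusted exact p = 0.775). For the others, distances were taken to the nearest transcript start of the gene and not to its body. The summits nearest to a start were 2041 bp from that of lab (214), 17640 bp for pb (30499), 11598 bp for Dfd (789), 4559 bp for Scr (910), 12380 bp for Antp (3605), 14318 bp for Ubx (18799) and 3331 bp for abd-A (201). Within gene bodies, Antp held 4 peaks, the strongest at 25536, Abd-B held 4, pb 2, and lab and Ubx 1 each, while Dfd, Scr and abd-A held none.

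The bithorax complex, the Hox cluster of Ubx, abd-A and Abd-B (3R from 16656623 to 16972236), held 19 peaks, 9 of them with the motif. That is 6.02 per 100 kb (exact Poisson 95% interval 3.62 to 9.40) against 4.07 over the arms, the 80.1st percentile of windows of the same length. Among the 2721 strongest peaks the density was 5.07 per 100 kb, the 99.0th percentile. The sites were unevenly placed: inside the 77804 bp of Ubx there was only a weak intronic peak at 16704324 (720). Going on toward Abd-B, strong summits stood at 16748744 in an intron of lncRNA:bxd (18799) and at 16782588 near lncRNA:CR44945 (4448). The strongest of the complex, at 16798877 (37722), was intergenic near lncRNA:CR45750, lay between bxd and abd-A and had only a 1-mismatch motif. Beyond abd-A, 5 strong summits lay in introns of the noncoding gene lncRNA:iab8, at 16834849 (9766), 16857212 (11228), 16869376 (22323), 16882746 (9574) and 16919232 (17829), all with the motif. Inside Abd-B, intronic summits stood at 16934913 (8670), 16957957 (20404, with no motif) and 16969727 (19198). The weaker peaks were at 16764170, 16784114, 16833380, 16847400, 16899235, 16899456 and 16933524, with signals from 196 to 682.

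**Figure D4:**
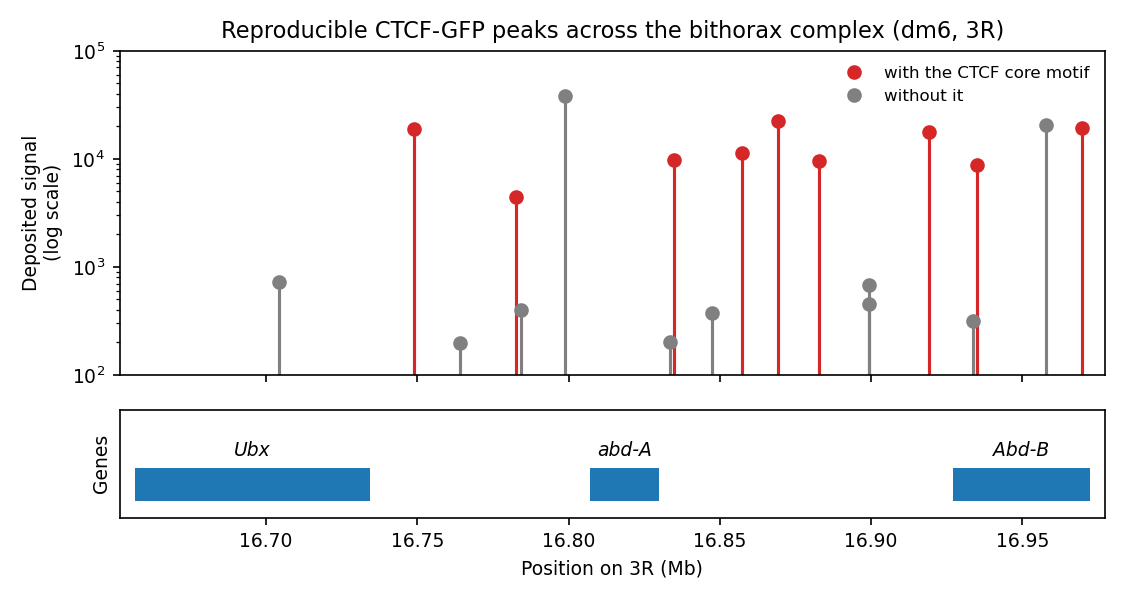
Map of the bithorax complex on 3R (horizontal axis, Mb, dm6) with the 19 reproducible summits drawn at their deposited signal on a log scale, red with the CTCF core motif and grey without, above the spans of Ubx, abd-A and Abd-B. The 9 motif peaks have signals between 4448 and 22323, and the highest summit, 37722, lies between Ubx and abd-A.

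CTCF sites were spread over X and the autosomes at similar density. X had 42.9 peaks per Mb and the arms 2L, 2R, 3L and 3R together 40.4, a ratio of 1.06 (95% interval 0.990 to 1.14) that did not pass the two-sided exact binomial test (p = 0.0878). The result rests near the threshold: the ratio was 1.09 in replicate 2 alone (exact p = 0.0171), 1.03 in replicate 3 alone (exact p = 0.413) and 1.11 among the 2721 strongest peaks (exact p = 0.0365). Chromosome 4, small and largely heterochromatic, had 24.5 peaks per Mb (exact Poisson 95% interval 16.8 to 34.4), below the 39.1 to 42.9 of the other arms.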

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

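The tests of arm ratios between the builds and of windows with similar numbers of transcript starts were chosen only after the result was seen.

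On the older build, 9 of the 4845 reproducible peaks lay outside the chromosome arms: 3 on XHet, 3 on 3RHet, 2 on U and 1 on 3LHet. Their signals ran from 231 to 1544, the highest on XHet, and the dm6 list held no peak off the arms.

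The CTCF gene held the third strongest peak of its own protein. The exact CTCF core motif lay 26 bp from the summit, which is in line with direct binding. Extra copies of the locus from the transgene could raise the signal there, and relaxed peaks outside the reproducible set were dense within 10 kb of the gene, with 13 against a median of 3 in windows of that length, the 96.0th percentile. But the other 19 strongest peaks had a median of 13 such peaks around them, and 9 of the 19 had fewer than the CTCF gene, so that density does not single out the locus. Among 320 windows with a similar number of transcript starts the CTCF gene stood at a percentile of 95.2, too close to the bound set for that test to exclude gene density; extra copies and gene density both stay open, and no biological explanation was tested.

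Most reproducible peaks lacked the CTCF motif. Peaks without the exact motif carried it with 1 mismatch only 8.80 percentage points more often than their flanks (95% interval 7.72 to 9.88). That argues against 1 mismatch as the main reason, although the upper bound lay just under the limit set for the test. In the strongest 10th of all peaks the mismatch raised the motif share from 50.6% to 82.9%. Looser forms were not tried, so too strict a motif is not excluded for the peaks that lacked it. Of these peaks 66.8% were at promoters, against 23.6% of shifted summits and 34.5% of peaks with the motif, which is consistent with signal that belongs to promoters. The share without the motif was 98.9% in the weakest 10th of the peaks and 49.4% in the strongest, as peaks near the detection limit would give. Whether CTCF is held at these promoters by other proteins, or promoters are enriched in any such precipitation, stays open, since no sample without the tag was used here and no biological explanation was tested.

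The newer build gave 5443 reproducible peaks and the older 4845. A gain confined to added sequence is argued against, because the lowest ratio over X, 2L, 2R, 3L and 3R was 1.12. The ratios did not differ between these arms (chi-square p = 0.999). Both lists come from the same reads, so their counts are not independent and that p-value carries little weight. A lower threshold may account for most of the gain: 4985 dm6 peaks reached the lowest dm3 signal, 2.89% above the dm3 count. That excess lies between the bounds set for the test, and signal scales of the builds may differ, so the threshold and the build cannot be told apart here.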

How the results depend on the processing

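Motif-only gene lists, merged overlaps, local shifts and all settings for feature classes, other motifs and motif share by rank were chosen only after the result was seen. Transfer RNA genes turned direction, with an odds ratio of 0.926 in the main test (not past it), 0.513 at 200 bp and 2.00 within gene length quintiles, past the test in both. Hox, gap and pair-rule, segment polarity, proteasome, neuronal and muscle genes also crossed an odds ratio of 1 in some settings, past the test in none. With motif peaks only, the odds ratio was 0 for Polycomb and Trithorax (2.74 in the main test), mitochondrial ribosomal protein (1.82) and dosage compensation genes (3.10). None of these passed the test in that setting. The promoter share, CTCF motif share, spacing, head-to-head share and the odds ratio for motif and promoter position kept direction and side of the threshold under every setting run. The replicate correlation (rho) moved to 0.893 with summits within 50 bp, 0.849 within 250 bp and 0.881 with overlapping intervals. The ratio of X to autosomal density ranged from 1.03 to 1.09 with 1 replicate left out, passed the test without replicate 3 (1.09), and rose to 1.11 among the 2721 strongest peaks. With motif peaks only, 0 gene lists were higher and 0 lower by Fisher's exact test after adjustment, with fewer peaks as part of the construction; at an unadjusted p under 0.05 there were 2 and 0. The number of motifs rarer at summits, 1 (Zelda), fell to 0 among the 2721 strongest peaks and was 0 to 0 with either replicate left out. At an unadjusted p under 0.05 these counts were 0 among the strongest, 0 without replicate 2 and 1 without replicate 3, where the motif was GAGA (1.47% against 2.06%, exact McNemar p = 0.0462) and not Zelda. Zelda had exact McNemar p = 0.405, 0.0919 and 0.0534 in these settings, and the cause was not tested for any of them. Local shifts put 7 feature classes past the test in place of 5, and a repeat with other draws gave permutation p = 0.0659 for 5' UTRs and 0.0539 for other exons, so these lie at the threshold. The strongest pooled peaks with no IDR step were the same 5443 peaks, so that setting tested nothing. Peak density on dm3 was not run, because arm lengths of that build were not used here. No paired analysis was possible because there was 1 group. Read depth is not given in the sources used here, so weak peaks cannot be placed relative to a detection limit in reads.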

Other observations

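All tests in this part were chosen only after the peaks had been examined.

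CTCF sites with the core motif were denser on X than on the autosomes, which the sites without it were not. X held 7.43 motif peaks per Mb and the arms 2L, 2R, 3L and 3R 4.69, a ratio of 1.59 (95% interval 1.33 to 1.89, exact binomial p = 4.04e-07), while peaks without the motif stood at 35.4 and 35.7 per Mb (ratio 0.993, 0.920 to 1.07, exact p = 0.864). The motif share of peaks was 17.3% on X and 11.6% on the autosomes (odds ratio 1.60, Fisher's exact p = 2.15e-06). The X sequence itself held more copies of AGRKGGCGC, 28.2 per Mb against 20.6 (ratio 1.37, 1.25 to 1.49, exact p = 4.53e-12). Of these copies 28.9% on X and 24.1% on the autosomes lay within 50 bp of a reproducible summit (Fisher's exact p = 0.0146). By genes the chromosomes did not pass a test: 24.9% of X genes and 24.4% of autosomal genes had a peak near a transcript start (Fisher's exact p = 0.610).

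Of the 2929 copies of the CTCF core on the arms, 740 (25.3%) lay within 50 bp of a reproducible summit. Copies within 1 kb of a transcript start were occupied more often, 261 of 848 (30.8%) against 479 of 2081 farther away (23.0%; odds ratio 1.49, Fisher's exact p = 1.57e-05), although most motif peaks were away from promoters.

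In promoter peaks without the CTCF core, the DRE, Motif 1 and Ohler 6 promoter motifs recurred. At least 1 of these 3 was within 50 bp of the summit in 280 of 3176 promoter peaks (8.82%) and 18 of 1575 others (1.14%; odds ratio 8.36, Fisher's exact test, adjusted p = 2.19e-30 over 4 tests). DRE was in 136 of the promoter peaks (4.28%) and 9 of the others (0.571%), and Motif 1 in 127 and 5. DRE, Motif 1 and Ohler 6 are promoter motifs, and promoters without a peak were not compared. These differences therefore do not tell promoters with a CTCF site from promoters at large. Every 8-base sequence was counted in peaks without the core and ranked by its excess over the flanks. First were ATCGATAG (3.05% of summits, 0.274% of flanks) and TATCGATA (3.05%, 0.305%), both of the DRE. Then came AAGTATGC (3.01%, 0.295%), whose other strand overlaps the su(Hw) core YTGCATAYY, and GGTCACAC (2.78%, 0.274%), which is Motif 1. The su(Hw) core itself was in 2.50% of peaks without the CTCF core against 0.737% of their flanks. Its share by promoter position was not tested. Some others, such as AAAATGTA (3.54%, 1.43%), had a higher share at summits but a smaller excess. In all peaks the first was AGATGGCG (7.13%, 0.294%), part of the CTCF core.

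Neighbouring CTCF motifs 5 to 50 kb apart showed no difference between the opposed orientations that passed a test. Of 156 such pairs of motif peaks 31 pointed toward each other and 38 away (exact binomial p = 0.470). Over all 686 neighbouring pairs 169 pointed toward each other and 169 away. Along an arm these kinds of pair must alternate, so near equality over all pairs was fixed in advance and tests nothing.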
